A study of Mus musculus with 8 samples.

How the data were processed

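RNA of single cells from mouse lungs after bleomycin was measured in 4 RNA libraries, 1 for each of 2 days (14 and 24) and 2 sorts (PDPN and pooled), each with a matching hashtag library. The matrices deposited by the authors hold raw UMI counts per gene and cell barcode, with the hashtag UMI counts of the same barcodes, and were checked to hold whole numbers. Per the submitters' processing notes they were made with Cell Ranger 6.0.1 and bcl2fastq on build GRCm38. The annotation version and whether intronic reads were counted are not given in the sources used here. A note of the authors in the feature reference lists the hashtags of each library and the number of mice: hashtags 1, 2 and 3 for 3 mice at day 14, and hashtags 1, 2, 4 and 5 for 4 mice at day 24. The libraries held 11136 (PDPN, day 14), 11808 (PDPN, day 24), 11015 (pooled, day 14) and 10708 (pooled, day 24) barcodes, with a median of 7690, 7502, 5272 and 5209 UMIs.

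Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept (10368, 11421, 10170 and 10061 cells in the order above). Each cell was assigned to hashtags by a threshold per hashtag (Otsu's method on log10 UMIs, scikit-image 0.26.0), and cells with more than 1 hashtag were removed as doublets between mice (844, 904, 978 and 756 cells). Doublets within a mouse were scored by Scrublet as implemented in scanpy. Its automatic threshold called 0, 0, 478 and 228 cells, and after this was seen it was replaced by the score at which the number of calls met the number of within-mouse doublets that the hashtags predict (427, 302, 491 and 254), with 482, 314, 512 and 260 cells called. Cells without a hashtag call were kept for clustering and pooled shares (2.26%, 1.13%, 4.22% and 3.81% of the cells kept) and left out of all values per mouse. Their share was larger in some classes. Of 726 fibroblasts of the pooled sort at day 14, the 3 mice had 183, 180 and 98. Of 562 at day 24, the 4 mice had 118, 122, 146 and 55.

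Cells of each sort were normalised to their total, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0 were used, first for compartments and then within each. Clusters were named from markers of 48 cell types fixed before the data were examined, and are given as "like" the type. The rule that turns markers into names went through 5 versions while clusters and their sizes by day were in view, and the earlier 4 are among the alternatives. Clusters that met no name made up 14.7%, 9.31%, 20.2% and 22.4% of cells and were left out of the comparisons of single named classes. All fibroblasts and blood endothelium taken as 1 class included the clusters without a name of their compartment. The general capillary share was left out because large endothelial clusters had no name. The class named for inflammatory fibroblasts was led by interferon-induced genes, and the class named for CD8 T cells also held genes of natural killer cells.

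Shares were computed within a compartment, pooled with exact binomial 95% intervals and per mouse, and compared by an exact permutation test over the 35 splits of the 7 mice. That test was added once the note on mice had been read. For genes, UMIs were summed per mouse and class in classes of at least 200 cells on each day and tested by edgeR quasi-likelihood F tests (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05), day 24 against day 14 with 4 and 3 mice, a test that was planned for the case that hashtags mark mice. SE of a log2 change is that of the fitted coefficient. Differences in the day effect between 2 classes of the same mice were tested by an edgeR fit with mouse as a block and a term for class by day. The 25 gene lists were fixed before the data were examined and were tested by camera with a preset correlation of 0.01 and again with an estimated correlation, where at least 5 members were tested. CPM are UMI counts scaled to the total of the class, and means and SD are over mice.

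Genes were named by a rule fixed before the data were examined. A gene needed at least 50 UMIs over both libraries, at least 25 CPM on 1 day and at least 10% of its highest CPM in any other class of the same library, and mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, sex-linked and predicted genes were left out. The 10 highest and 10 lowest by log2 ratio with 5 CPM added, at least 2-fold changed and with mice of the 2 days that did not overlap, were eligible, together with list members, of which examples are given. The 8 genes each way with the smallest adjusted p per class were added after the values were seen. Of the 361 genes named by these rules 357 had a position in the RefSeq table of GRCm38. Of the genes these rules or the clusters gave, 2 are not reported here.

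Precision was tested on simulated data, in which 100 genes were changed by 1.5-fold and 100 by 2-fold in each class. The changed genes were drawn from those with a mean of at least 25 CPM, so recovery of genes below that level was not measured. Among all fibroblasts 87 and 99 of these were recovered, among adventitial fibroblast-like cells 74 and 100, in blood endothelium 89 and 100, and in SPP1 macrophage-like, interstitial and alveolar macrophage-like cells 48 and 91, 35 and 92, and 40 and 86. Changes of 1.5-fold were thus often missed in macrophage classes at this depth and number of mice. Of the calls, 8.37% were false in all fibroblasts, 8.67% in alveolar and 8.54% in peribronchial fibroblast-like cells and 7.80% in blood endothelium, above the threshold of 5%, and between 3.47% and 6.95% in the other 5 classes simulated. The 6 smaller classes were not simulated. Each gene was drawn independently, so a difference between mice that many genes share was not simulated. The share of false calls in the real data may thus be higher than these rates.

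Alternatives were stricter and more lenient cell filters, no doublet removal, cells with 1 hashtag only, other resolutions and numbers of variable genes, TMM scaling of the pooled sums, other pseudocounts and CPM minimums, no screen against free RNA, cells thinned to 2000 UMIs, means over cells, equal weight per mouse and each mouse left out. Added after the data were seen were total UMI scaling, DESeq2, no low-count filter, no doublet removal, thinning and single mice left out for the edgeR counts, clustering without the genes that separate the days, and the earlier naming rules. Tools were Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.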

Results

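Lungs of mice given bleomycin, a drug that injures the lung and leads to scarring, were profiled by droplet-based single-cell RNA sequencing at day 14 and day 24. On each day, 1 library held cells sorted as CD45 negative, EpCAM negative and podoplanin positive (PDPN sort), and 1 library held pooled cells positive for CD45 (leukocytes), CD31 (endothelium) or EpCAM (epithelium) (pooled sort). Antibody hashtags marked the mouse of origin of each cell, which gave 3 mice at day 14 and 4 mice at day 24 in each sort. The question addressed was which cell classes and which genes within a class differed between the 2 days after bleomycin. No untreated lungs were among the libraries, and all cells of a day and sort passed through 1 capture, so each difference between days is also a difference between captures. The PDPN libraries held 96131198 UMIs at day 14 and 98911924 at day 24, and the pooled libraries 69685668 and 66347540. After filtering, 9042 cells at day 14 and 10203 at day 24 remained in the PDPN sort (median 7709 and 7347 UMIs per cell), and 8680 and 9045 in the pooled sort (median 5229 and 5199).

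The genes of the gates separated the 2 sorts on each day. Ptprc, which encodes CD45, stood at 0.390 CPM (UMI counts scaled to the library or class total) in the PDPN sort and 281 CPM in the pooled sort at day 14, and at 0.692 and 241 CPM at day 24. Epcam stood at 0.520 against 34.6 CPM and 0.862 against 71.9 CPM, and Pecam1, which encodes CD31, at 2.51 against 425 CPM and 1.75 against 500 CPM. Pdpn itself was 1.35-fold higher in the PDPN sort at day 14 (71.4 against 52.9 CPM) and 1.38-fold higher at day 24 (67.6 against 48.8 CPM). The collagen-binding proteoglycans Dcn (3107 against 116 CPM) and Lum (523 against 7.70 CPM) were among the genes with the largest ratio toward the PDPN sort at day 14. Those toward the pooled sort included Lyz2 (10.1 against 7278 CPM) and Cd74 (14.5 against 6698 CPM). Mesenchymal clusters made up 99.5% of PDPN cells at day 14 and 99.4% at day 24. The pooled sort held 49.1% immune, 39.1% endothelial, 9.45% mesenchymal and 2.27% epithelial cells at day 14, and 41.5%, 43.0%, 7.81% and 6.14% at day 24. The mixing of the 3 gates sets these sums, so class shares were compared only within a compartment.

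Fibrotic fibroblast-like cells, the class marked by Cthrc1, Postn, Tnc and Grem1, made up 12.1 ± 3.50% (mean ± SD) of mesenchymal PDPN cells at day 14 and 24.2 ± 5.68% at day 24 (exact permutation p = 0.0286, n = 3 and 4 mice). Pooled over mice this was 1081 of 9001 cells and 2468 of 10144 cells. The class combined 3 clusters that held different parts of it on the 2 days. A cluster led by Ibsp, Col10a1, Col11a1 and C1qtnf3 held 32.2% of the class at day 14 (348 cells) and 57.5% at day 24 (1419 cells). A cluster led by Spp1, Il11 and Inhba held 40.8% and 28.2%. Mural-like cells made up 5.52 ± 3.70% and 1.60 ± 0.663% (exact permutation p = 0.0571). Peribronchial fibroblast-like cells made up 13.5 ± 3.28% and 9.65 ± 2.96% (exact permutation p = 0.143). Adventitial fibroblast-like cells made up 29.1% and 24.3% and alveolar fibroblast-like cells 16.7% and 23.1% (exact permutation p = 0.543 and 0.143). Within the alveolar class, a cluster led by Lcn2, Gsta3, Mmp8 and Ccnd1 held 29.9% of cells at day 14 and 8.82% at day 24. Mesenchymal cells in clusters without a name made up 14.3 ± 2.28% and 9.29 ± 1.31% (exact permutation p = 0.0286). Of these a cluster with 637 and 473 cells was fibrotic under the first naming rule, by which the fibrotic difference was 9.63 points. The pooled sort held 820 mesenchymal cells at day 14 and 706 at day 24. Among them 127 and 124 were fibrotic and 376 and 163 alveolar fibroblast-like. Adventitial fibroblast-like cells numbered 26 and 18, peribronchial 8 and 17 and mural-like 81 and 113. The alveolar, peribronchial and mural shares there ran opposite to those of the PDPN sort, and none was tested.

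Among immune cells of the pooled sort, SPP1 macrophage-like cells, which express the secreted phosphoprotein osteopontin, made up 16.2 ± 4.97% at day 14 and 9.17 ± 2.47% at day 24 (exact permutation p = 0.0571, n = 3 and 4 mice, 686 and 347 cells). The SPP1 class included a cluster led by Saa3, Ccl24 and Alox15 (55 and 32 cells), which some of the earlier naming rules left without a name. Interstitial macrophage-like cells made up 12.3 ± 4.45% and 16.9 ± 2.04% (exact permutation p = 0.114) and alveolar macrophage-like cells 11.9% and 8.56% (p = 0.257). Mature dendritic-like cells made up 3.31 ± 0.743% and 2.24 ± 0.505% (exact permutation p = 0.0286, 140 and 84 cells). Among epithelial cells, club-like cells made up 3.39 ± 3.33% and 19.5 ± 4.86% (exact permutation p = 0.0286, 6 and 107 cells). The leading genes of the club class also included Krt5 and Krt15, markers of basal cells. Transitional epithelial-like cells made up 28.7 ± 2.56% and 12.7 ± 4.56% (exact permutation p = 0.0286, 60 and 81 cells), and epithelial cells in clusters without a name 28.7 ± 7.83% and 13.3 ± 3.84% (exact permutation p = 0.0286, 52 and 65 cells). AT2-like cells made up 8.58 ± 1.43% and 13.7 ± 2.77% and AT1-like cells 21.5% and 31.0% (exact permutation p = 0.0571 and 0.343). Among endothelial cells, lymphatic-like cells made up 1.58% and 3.05% (exact permutation p = 0.0571), aerocyte-like cells 14.0% and 13.5% (p = 0.886) and venous-like cells 7.43% and 6.56% (p = 0.2). The smallest p that the 35 splits of 7 mice can give is 0.0286, and none of the 32 classes passed after adjustment (smallest adjusted p = 0.203). The shares given were chosen after their values were seen. Without the genes that separate the days as input to clustering, the fibrotic share was 11.9% and 21.1%, and without doublet removal 11.2% and 20.02% (exact permutation p = 0.143 in each). Other share differences, day 24 minus day 14, depended on the settings. That of alveolar fibroblast-like cells turned to -2.74 points without those genes and -5.39 without doublet removal. That of AT1-like cells turned to -2.55 under the first naming rule and that of interstitial macrophage-like cells to -0.560 under the lenient filter. That of transitional epithelial-like cells was -6.92 at resolution 2. With 1 mouse left out the difference ranged from -5.66 to -1.98 points for mural-like, -8.89 to -4.20 for SPP1 macrophage-like and -8.46 to -0.415 for adventitial fibroblast-like cells. It ranged from 9.43 to 13.9 for fibrotic, 4.40 to 8.02 for alveolar and -5.25 to -2.06 for peribronchial fibroblast-like cells. It ranged from 2.12 to 6.41 for interstitial and -4.59 to -1.60 for alveolar macrophage-like cells, from 3.05 to 13.3 for AT1-like, -17.9 to -14.6 for transitional epithelial-like and 13.8 to 17.7 for club-like cells. In endothelium it ranged from 1.03 to 1.86 for lymphatic-like, -1.45 to -0.227 for venous-like and -1.77 to 1.02 for aerocyte-like cells.

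**Figure D1:**
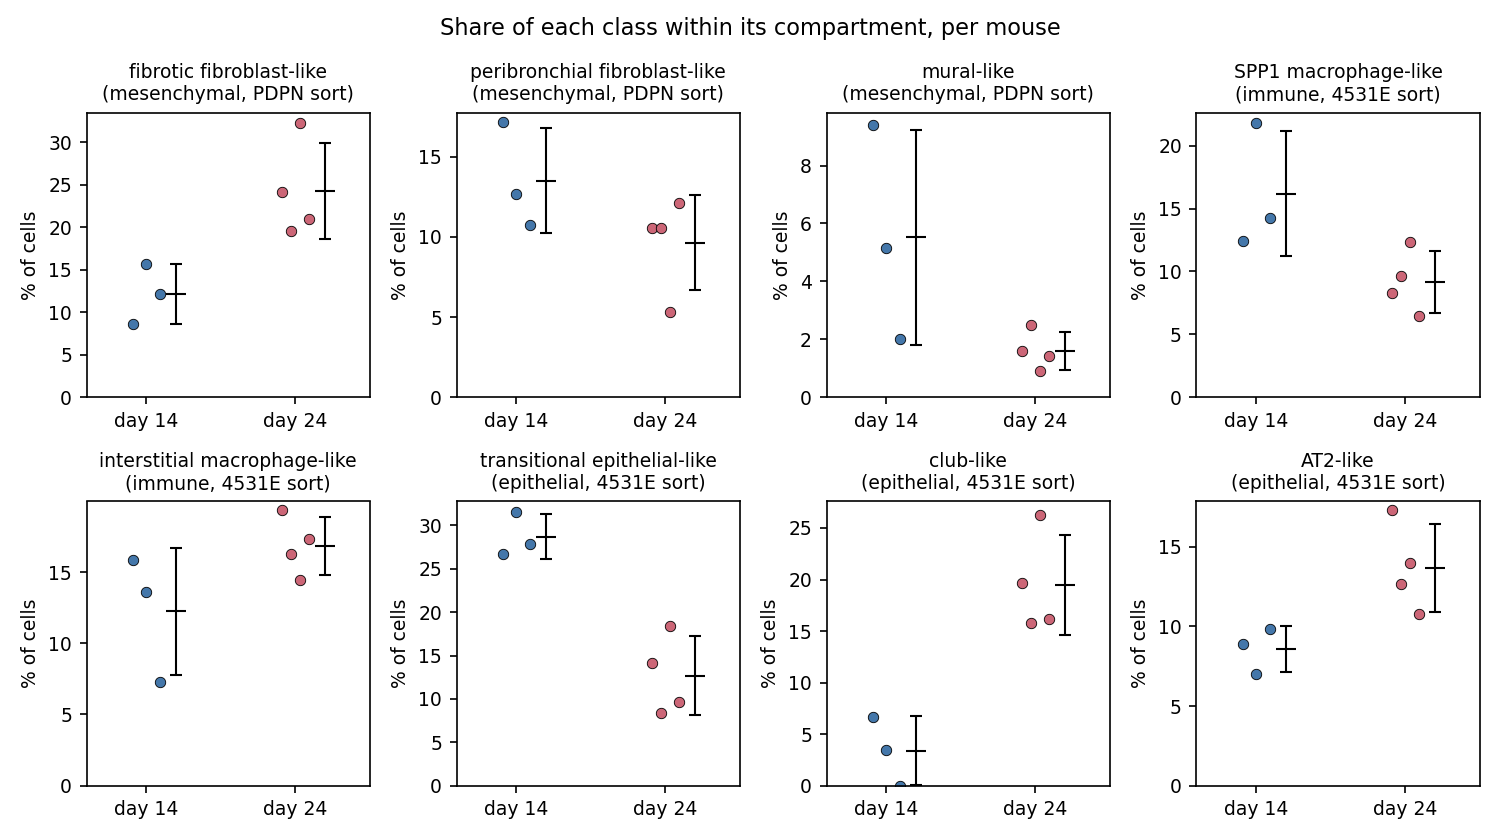
Share of 8 classes within their compartment (y axis, % of cells) at day 14 (3 mice) and day 24 (4 mice). Each point is 1 mouse, and lines show mean and SD, such as 12.1% and 24.2% for fibrotic fibroblast-like cells.

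In all fibroblasts of the PDPN sort taken as 1 class, 82 genes were higher at day 24 and 19 lower of 15332 tested. C1qtnf3 (ENSMUSG00000058914, chromosome 15, 10952119 to 10980162, GRCm38), a secreted C1q family protein, rose from 17.2 ± 3.34 to 56.1 ± 3.92 CPM (mean ± SD, log2 change 1.69 ± 0.11 SE, edgeR adjusted p = 0.0019, n = 3 and 4 mice). Grem1 (ENSMUSG00000074934, chromosome 2, 113748675 to 113758648), a BMP antagonist, rose from 106 ± 25.7 to 289 ± 48.6 CPM (1.43 ± 0.20, adjusted p = 0.0296). Dkk2 (ENSMUSG00000028031, chromosome 3, 132085266 to 132180304), a Wnt regulator, rose from 47.2 ± 7.63 to 118 ± 26.7 CPM (1.31 ± 0.18, adjusted p = 0.0296). The Wnt antagonist Frzb rose from 18.4 to 41.2 CPM (1.14 ± 0.08) and the growth factor Mdk from 161 to 263 CPM (0.69 ± 0.07). Pdgfa, which encodes a PDGF ligand, rose from 73.3 to 125 CPM (0.76 ± 0.12). The collagenase gene Mmp8 (ENSMUSG00000005800, chromosome 9, 7558429 to 7568486) fell from 44.0 ± 6.18 to 18.3 ± 4.67 CPM (-1.28 ± 0.19, adjusted p = 0.0354). Adam23 fell from 29.5 to 12.1 CPM (-1.31 ± 0.18), the cystine exchanger gene Slc7a11 from 4.53 to 1.13 CPM (-2.04 ± 0.25), Myc from 32.7 to 19.6 CPM (-0.76 ± 0.11) and Vgll3 from 90.9 to 69.4 CPM (-0.41 ± 0.06). Fbxo32, a ubiquitin ligase gene, rose by 0.61 ± 0.05. Col10a1, a collagen of hypertrophic cartilage, stood at 3.20 ± 4.11 and 29.7 ± 13.1 CPM (3.08 ± 0.75, adjusted p = 0.118) and did not pass. Ptx3 did not pass either (32.3 and 12.9 CPM, -1.38 ± 0.36, adjusted p = 0.138).

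The genes of scar matrix as a group did not move together in all fibroblasts. Of 23 genes of fibrillar and fibrosis matrix, 0 rose or fell by edgeR, over all genes or adjusted over the list alone. Col1a1 stood at 7923 and 7213 CPM (-0.16 ± 0.11, adjusted p = 0.524), Postn at 633 and 620 CPM (-0.05 ± 0.22) and Cthrc1 at 395 and 338 CPM (-0.24 ± 0.11). The median of the list was -0.03 and its mean 0.03. Matrix-degrading enzymes moved both ways: of 17 genes Mmp2 (0.42 ± 0.06) and Mmp11 (0.65 ± 0.08) rose and Mmp8 fell, against 3 and 1 adjusted over the list alone. Of 16 TGF-beta pathway genes the receptor Tgfbr2 rose (310 to 398 CPM, 0.34 ± 0.05), with 2 higher adjusted over the list alone. Of 14 p53 targets Mdm2 fell (-0.46 ± 0.07) and 6 fell adjusted over the list alone (camera adjusted p = 4.13e-06, adjusted p = 0.447 with an estimated correlation). A cluster without a name, led by Gdf15, Chchd10, Mdm2 and Cdkn1a, held 691 of 8332 fibroblasts at day 14 and 477 of 9726 at day 24. None of the 12 contractile genes passed (Acta2 1914 and 1529 CPM, -0.34 ± 0.12; list median -0.32, camera adjusted p = 0.00465, adjusted p = 0.447 with an estimated correlation). None of the 14 cell cycle genes passed (Mki67 42.6 and 27.2 CPM, -0.65 ± 0.33; list median -0.53, camera adjusted p = 5.82e-05, adjusted p = 0.447 with an estimated correlation). Of the 12 genes of dissociation and heat shock 7 rose adjusted over the list alone and 0 over all genes (list median 0.29). Leaving out 1 mouse at a time moved the number of called genes between 2 (without the day 24 mouse of hashtag 1 or of hashtag 2) and 184 (without that of hashtag 4). C1qtnf3 and Frzb kept their calls each time, and Grem1 and Dkk2 in 2 of the 7 cases. Fbxo32 did so in 5, Mdk in 4 and Slc7a11 in 3. Mmp8, Adam23, Myc, Mmp11, Mdm2 and Pdgfa kept theirs in 2, and Vgll3, Tgfbr2 and Mmp2 in 1. Dkk2, Adam23, Tgfbr2, Mmp11 and Mdm2 did not pass after each cell was thinned to 2000 UMIs, nor Mdm2 under total UMI scaling. Frzb, Mdk, Slc7a11, Myc, Fbxo32 and Vgll3 were named after their values were seen.

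**Figure D2:**
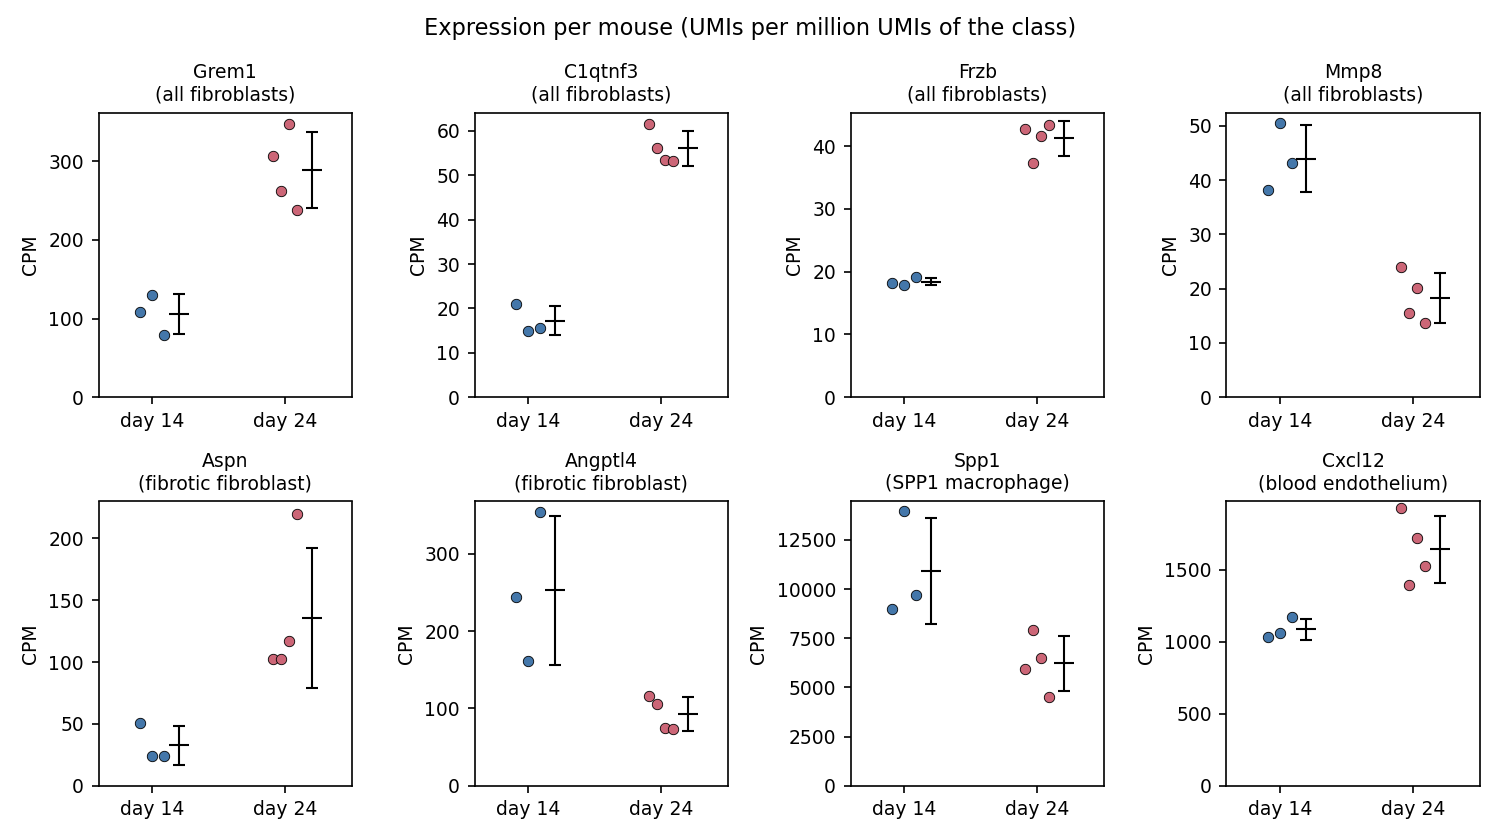
Expression of 8 genes in CPM of the class (y axis) at day 14 (3 mice) and day 24 (4 mice), with mean and SD, such as 106 and 289 for Grem1 in all fibroblasts. Each point is 1 mouse.

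In alveolar fibroblast-like cells, 90 genes were higher and 73 lower of 11470 tested. The BMP antagonist Nbl1 (ENSMUSG00000041120) rose from 382 ± 47.9 to 724 ± 45.2 CPM (log2 change 0.89 ± 0.09 SE, edgeR adjusted p = 0.00271, n = 3 and 4 mice) and Rgs16, a regulator of G protein signalling, from 38.8 to 124 CPM (1.60 ± 0.30, adjusted p = 0.0233). Mmp8 fell from 112 ± 30.1 to 34.8 ± 9.05 CPM (-1.72 ± 0.20, adjusted p = 0.00426) and cyclin D1 (Ccnd1, ENSMUSG00000070348) from 146 to 89.9 CPM (-0.74 ± 0.09, adjusted p = 0.00426). The protease inhibitor Timp1 fell from 1383 to 630.0 CPM (-1.17 ± 0.21), Wisp1 from 123 to 82.5 CPM (-0.62 ± 0.09) and Tnnt2 from 26.3 to 10.7 CPM (-1.35 ± 0.25). Mmp8 and Ccnd1 also led the smaller cluster of this class, which held 29.9% of it at day 14 and 8.82% at day 24. What this shift adds to the changes of the class was not tested. Of 12 genes of dissociation and heat shock 8 rose and 10 adjusted over the list alone (camera adjusted p = 7.73e-19, adjusted p = 0.186 with an estimated correlation). They included Hspa1a (685 to 1129 CPM, 0.69 ± 0.09), Hspa1b (332 to 537 CPM, 0.66 ± 0.08), Dnajb1 (274 to 493 CPM, 0.81 ± 0.12) and the immediate early genes Fos (0.57 ± 0.11), Jun (0.53 ± 0.09) and Egr1 (0.55 ± 0.11). Of 14 p53 targets Ccng1 (-0.54 ± 0.11) and Bax (-0.34 ± 0.07) fell and 7 fell adjusted over the list alone (camera adjusted p = 5.54e-08, adjusted p = 0.186 with an estimated correlation). Of 12 interferon response genes Isg15 (-0.42 ± 0.09) and Bst2 (-0.48 ± 0.10) fell, also adjusted over the list alone (camera adjusted p = 0.00612, adjusted p = 0.791 with an estimated correlation). Of 22 matrix genes 2 rose, Thbs2 (22.3 to 38.7 CPM, 0.76 ± 0.11) and, at under 10% of its level in another class, Aspn (1.31 ± 0.27), and the list median was -0.01 with a mean of 0.08. The protease gene Mmp11 (20.8 to 39.6 CPM, 0.92 ± 0.15), the receptor gene Tgfbr2 (0.36 ± 0.07) and the lipase gene Lpl (0.40 ± 0.09) rose. Without the day 14 mouse of hashtag 3 no gene passed by edgeR. Without doublet removal Rgs16, Mmp8, Tnnt2, Wisp1, Thbs2, Mmp11, Tgfbr2, Lpl, Ccng1, Bax, Isg15 and Bst2 did not pass. After thinning Tnnt2, Thbs2, Lpl, Ccng1, Bax, Isg15 and Bst2 did not pass, and the last 4 did not under total UMI scaling either. Tnnt2, Thbs2 and Mmp11 had no result with DESeq2. With 1 mouse left out Tgfbr2, Lpl, Bax, Isg15 and Bst2 passed in 1 of 7 cases. Nbl1, Ccnd1 and Wisp1 were named after their values were seen.

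In adventitial fibroblast-like cells no gene passed by edgeR (11953 tested). At an unadjusted p under 0.05 there were 833 higher and 864 lower genes, and DESeq2 called 59 higher and 91 lower. The largest differences that separated the mice of the 2 days were Mrgprg, a receptor gene (0.540 and 38.7 CPM, log2 change 6.21 ± 1.01 SE, edgeR adjusted p = 0.0721, n = 3 and 4 mice) and the sphingomyelinase gene Smpd3 (13.7 and 93.8 CPM, 2.79 ± 0.56, adjusted p = 0.0806). Fbln7 (1.33 ± 0.25) and Daglb (11.2 and 34.9 CPM, 1.67 ± 0.37) followed. Mrgprg and Smpd3 led 1 of the 4 clusters of this class. Lower at day 24, without passing, were Cthrc1 (474 and 252 CPM, -0.95 ± 0.21) and Angptl4 (97.4 and 43.7 CPM, -1.15 ± 0.26). Of 23 matrix genes 0 passed over all genes and 5 fell adjusted over the list alone (list median -0.23, camera adjusted p = 7.18e-07, adjusted p = 0.34 with an estimated correlation). Of 12 contractile genes 7 fell adjusted over the list alone (median -0.50, camera adjusted p = 1.93e-07, adjusted p = 0.272 with an estimated correlation). Of 16 genes of collagen processing 5 fell so (median -0.21, camera adjusted p = 0.000198, adjusted p = 0.219 with an estimated correlation) and of 14 interferon genes 4 (median -0.40, camera adjusted p = 3.92e-05, adjusted p = 0.34 with an estimated correlation). Of 5 MHC class II genes 4 rose adjusted over the list alone (median 1.67, between 0.85 and 2.06 without 1 mouse). Leukocyte genes were also higher at day 24 over the whole PDPN library, such as Lyz2 (10.1 and 24.2 CPM), Cd74 (14.5 and 28.2 CPM) and Ptprc. Without the day 24 mouse of hashtag 4 edgeR called 37 higher and 69 lower genes, and without the day 14 mouse of hashtag 1 it called 11 and 24.

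In peribronchial fibroblast-like cells, which formed a single cluster, 145 genes were higher and 85 lower of 10428 tested. Scaled by total UMIs these were 167 and 57. Dkk2 rose from 38.6 to 152 CPM (log2 change 1.95 ± 0.20 SE, edgeR adjusted p = 0.000153, n = 3 and 4 mice). The phospholipid transfer gene Pltp (ENSMUSG00000017754, chromosome 2, 164839518 to 164857708) rose from 119 ± 4.70 to 265 ± 12.6 CPM (1.12 ± 0.08, adjusted p = 4.98e-06) and C1qtnf3 from 1.85 to 16.5 CPM (3.09 ± 0.34). Ptch1, the Hedgehog receptor and a target of that pathway, rose from 66.1 to 165 CPM (1.30 ± 0.21, adjusted p = 0.00622), and the Wnt inhibitor Nkd2 from 11.5 to 34.4 CPM (1.63 ± 0.26). Grem1 (155 to 342 CPM, 1.11 ± 0.18), Tmem119 (15.2 to 48.8 CPM, 1.65 ± 0.21), Thy1 (9.34 to 28.1 CPM, 1.68 ± 0.26), Cpxm2 (1.93 ± 0.31) and Fam198b (1.39 ± 0.23) rose as well. So did the natriuretic peptide receptor gene Npr3 (155 to 284 CPM, 0.85 ± 0.09) and Mdk (83.6 to 171 CPM, 0.99 ± 0.11). Ankrd1, a target of YAP signalling, fell from 44.0 to 15.9 CPM (-1.43 ± 0.20), and the cadherin gene Cdh4, a marker used to name this class, from 52.3 to 23.6 CPM (-1.19 ± 0.21). Plpp3 fell from 272 to 157 CPM (-0.84 ± 0.10), the TWEAK receptor gene Tnfrsf12a from 286 to 181 CPM (-0.70 ± 0.09) and Myc from 49.7 to 30.3 CPM (-0.74 ± 0.12). Of 22 matrix genes 3 rose and 1 fell, and 5 and 1 adjusted over the list alone. Fn1 (883 to 1413 CPM, 0.64 ± 0.11) and Col8a1 (1.07 ± 0.24) were higher and Eln (5414 to 3692 CPM, -0.59 ± 0.11) lower. Of 16 TGF-beta pathway genes Tgfbr2 (0.45 ± 0.08) and Itgb5 (0.50 ± 0.09) rose, and 5 rose and 2 fell adjusted over the list alone. The proteases Mmp2 (235 to 418 CPM, 0.79 ± 0.11) and Ctsk (104 to 170 CPM, 0.67 ± 0.14) rose. The p53 targets Mdm2 (-0.53 ± 0.13) and Plk2 (-0.66 ± 0.14) fell, 2 of 14 over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.516 with an estimated correlation). Mir6236, a transcript that overlaps ribosomal RNA, rose by 1.08 ± 0.09. Col8a1 and Ctsk did not pass without doublet removal, nor Nkd2, Fam198b, Itgb5, Mdm2 and Plk2 after thinning. C1qtnf3 and Thy1 had no result after thinning. Mdm2 did not pass under total UMI scaling or with DESeq2 either. Every gene named for this class except Eln, Col8a1, Tgfbr2, Itgb5, Mdm2, Plk2 and Ctsk passed with any 1 mouse left out. The number of called genes moved between 58 (without the day 14 mouse of hashtag 2) and 373 (without the day 24 mouse of hashtag 4). C1qtnf3, Mdk, Npr3, Plpp3, Tnfrsf12a and Myc were named after their values were seen.

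In fibrotic fibroblast-like cells 74 genes were higher and 45 lower of 11811 tested. The clusters of this class held different parts of it on the 2 days, and what that adds to these changes was not tested. Grem1, also 1 of the markers used to name this class, rose from 275 ± 11.8 to 620 ± 48.1 CPM (log2 change 1.14 ± 0.08 SE, edgeR adjusted p = 0.000327, n = 3 and 4 mice). Aspn (ENSMUSG00000021388, chromosome 13, 49544443 to 49567565), a small leucine-rich matrix protein, rose from 32.9 ± 15.8 to 135 ± 56.6 CPM (2.07 ± 0.33, adjusted p = 0.0194). The water channel gene Aqp1 rose from 40.3 to 106 CPM (1.36 ± 0.13), the tetraspanin gene Cd9 from 141 to 308 CPM (1.09 ± 0.11), Pltp from 171 to 405 CPM (1.22 ± 0.23) and the Wnt modulator Sfrp2 from 24.1 to 64.6 CPM (1.29 ± 0.25). Dkk2 (1.09 ± 0.21) and the cell cycle inhibitor Cdkn2a (16.2 to 42.7 CPM, 1.31 ± 0.15) rose too. Pla2g7 rose from 3.73 to 14.5 CPM (2.03 ± 0.24), and Mir6236 rose by 1.09 ± 0.10. C1qtnf3 stood at 65.8 and 138 CPM (1.08 ± 0.26, adjusted p = 0.0838) and did not pass. Angptl4, a lipase inhibitor, fell from 253 to 92.3 CPM (-1.49 ± 0.24, adjusted p = 0.0194). Tnnt2 (104 to 48.7 CPM, -1.15 ± 0.17) and Mmp8 (-2.29 ± 0.23) fell. Npnt, a marker of alveolar fibroblasts, fell from 217 to 139 CPM (-0.68 ± 0.08) and Thbs1, an activator of TGF-beta, from 2953 to 1939 CPM (-0.64 ± 0.08). Ankrd1 (-1.52 ± 0.31, adjusted p = 0.05) did not pass.

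In the fibrotic class single members of the gene lists moved in several directions. Of 23 matrix genes Aspn rose, and 3 rose adjusted over the list alone, with a list median of -0.01 and a mean of 0.20. Of 12 contractile genes Tagln fell (3195 to 2225 CPM, -0.56 ± 0.11), and 5 fell adjusted over the list alone (camera adjusted p = 1.55e-05, adjusted p = 0.556 with an estimated correlation). In the TGF-beta pathway Tgfbi rose (34.3 to 66.7 CPM, 0.95 ± 0.12), while Tgfb2 fell (193 to 122 CPM, -0.71 ± 0.13), and 1 rose and 3 fell adjusted over the list alone. Of 16 genes of matrix degradation Ctsk rose (143 to 225 CPM, 0.62 ± 0.07), and Adamts1 (266 to 161 CPM, -0.77 ± 0.15) was 1 of 2 that fell, against 5 and 4 adjusted over the list alone. Of 12 genes of the SPP1 macrophage list that fibroblasts also express 3 rose, among them Cd9, Pdgfa (135 to 241 CPM, 0.81 ± 0.10) and Ctsk, and 5 adjusted over the list alone (camera adjusted p = 7.51e-06, adjusted p = 0.0635 with an estimated correlation). Mdm2 fell (-0.73 ± 0.12), 1 of 14 p53 targets, and 6 fell adjusted over the list alone (camera adjusted p = 1.31e-05, adjusted p = 0.454 with an estimated correlation). Serpinf1, a gene of adventitial identity, rose (130 to 222 CPM, 0.74 ± 0.14). Of 12 cell cycle genes 0 passed over all genes and 1 fell adjusted over the list alone (median -0.64, camera adjusted p = 1.77e-05, adjusted p = 0.578 with an estimated correlation). Tgfb2, Mdm2 and Serpinf1 did not pass without doublet removal, nor Cdkn2a, Pla2g7, Pdgfa and Mdm2 after thinning, nor Tagln under total UMI scaling. Dkk2 passed in 1 of 7 cases with 1 mouse left out. Aqp1, Grem1, Cd9, Cdkn2a, Mir6236, Ctsk, Pla2g7, Mmp8 and Npnt passed with any 1 mouse left out. The number of called genes moved between 14 (without the day 14 mouse of hashtag 3) and 463 (without the day 24 mouse of hashtag 4). Pla2g7, Mmp8, Thbs1 and Npnt were named after their values were seen.

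**Figure D3:**
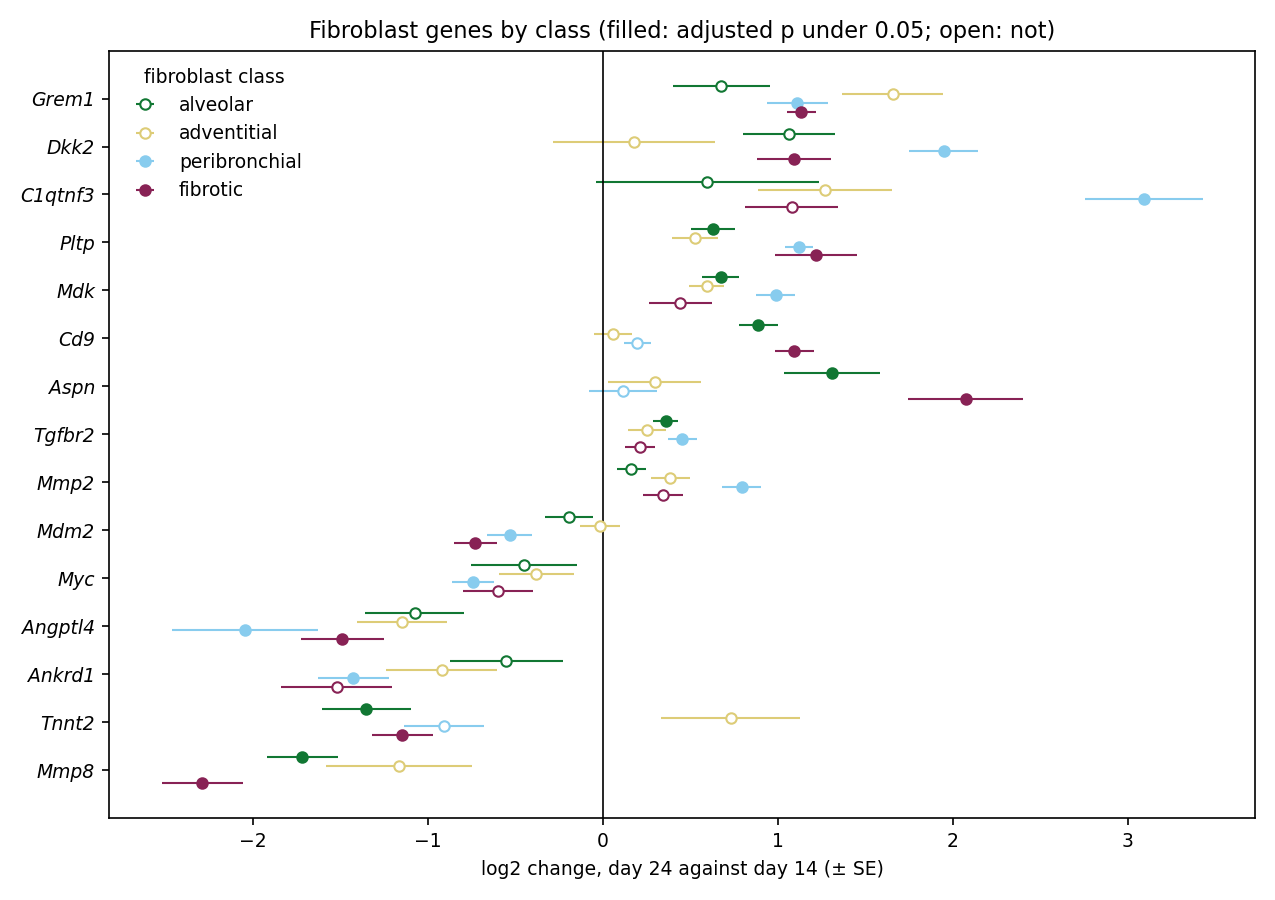
Log2 change from day 14 to day 24 (x axis, ± SE) of 15 genes in 4 fibroblast classes of the PDPN sort (3 and 4 mice), such as 1.14 for Grem1 in fibrotic fibroblast-like cells. Filled points have an edgeR adjusted p under 0.05, and Aspn and Cd9 in alveolar fibroblast-like cells are filled although their level there was under 10% of that in another class.

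The effect of day was compared between classes by a test of the difference itself. Between alveolar and adventitial fibroblast-like cells 17 genes differed in their change. Hspa1a 0.70 ± 0.09 SE (edgeR adjusted p = 0.0121) and Dnajb1 0.61 ± 0.10 were higher and Ccnd1 -0.94 ± 0.15 lower in the alveolar class. Between fibrotic and alveolar fibroblast-like cells 29 genes differed, with Pdgfa 0.75 ± 0.14 higher and Rgs16 -1.42 ± 0.27, Npnt -0.70 ± 0.11 and Thbs1 -0.57 ± 0.11 lower in the fibrotic class. Between peribronchial and adventitial fibroblast-like cells 65 genes differed, while another of the 35 splits of the mice gave 113. Tmem119 1.74 ± 0.25, Thy1 1.60 ± 0.28, Cthrc1 1.21 ± 0.18 and Fn1 0.76 ± 0.10 were higher and Plpp3 -0.97 ± 0.15 lower in the peribronchial class. The 3 pairs of classes were chosen after their calls were seen.

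In blood endothelium of the pooled sort 59 genes were higher and 71 lower of 11917 tested. Of these, 53 higher and 35 lower genes reached at least 10% of their highest level in any other class of the same library, a screen against free RNA. Scaled by total UMIs 43 genes were higher and 113 lower. Per1 (ENSMUSG00000020893, chromosome 11, 69095108 to 69109965), a gene of the circadian clock, fell from 68.5 ± 9.70 to 29.7 ± 3.96 CPM (log2 change -1.15 ± 0.12 SE, edgeR adjusted p = 0.00142, n = 3 and 4 mice). Mal (ENSMUSG00000027375), a membrane raft protein, rose from 24.0 ± 7.25 to 73.7 ± 26.7 CPM (1.65 ± 0.28, adjusted p = 0.0226) and Ildr2 from 16.6 to 40.3 CPM (1.31 ± 0.19, adjusted p = 0.0106). Mal also led a cluster that held 273 of the 3255 cells of blood endothelium at day 14 and 583 of 3714 at day 24. The chemokine gene Cxcl12 rose from 1088 to 1642 CPM (0.64 ± 0.11), the aryl hydrocarbon receptor gene Ahr from 187 to 285 CPM (0.66 ± 0.07) and Tnfrsf11b, which encodes osteoprotegerin, from 23.0 to 42.8 CPM (0.93 ± 0.14). The clotting gene Vwf fell from 1288 to 755 CPM (-0.72 ± 0.14) and the phosphatase gene Dusp8 from 123 to 67.3 CPM (-0.82 ± 0.09). The survival gene Bcl2l1 fell from 78.6 to 50.1 CPM (-0.60 ± 0.07) and the scavenger receptor gene Stab1 from 107 to 65.0 CPM (-0.67 ± 0.09). Of 14 genes of endothelial activation 1 fell, also adjusted over the list alone (list median -0.16, camera adjusted p = 0.2). Of 10 general capillary genes 1 rose (median 0.05) and of 10 aerocyte genes 0 passed over all genes and 1 fell adjusted over the list alone. Genes typical of other cells moved too, below the 10% screen. Spp1 fell from 114 to 33.9 CPM (-1.71 ± 0.09, adjusted p = 4.88e-06), Apoe from 269 to 129 CPM (-1.01 ± 0.06) and Mmp12 from 25.8 to 8.15 CPM (-1.63 ± 0.16), and the surfactant gene Sftpc rose (1.83 ± 0.17). Of 13 genes of the SPP1 macrophage list 5 fell, also adjusted over the list alone (camera adjusted p = 2.58e-21, adjusted p = 0.0034 with an estimated correlation). Of 18 matrix genes 2 fell, Bgn (-0.88 ± 0.17) and Fn1 (-0.75 ± 0.13), against 8 lower and 1 higher adjusted over the list alone. With 1 mouse left out Bgn passed in 1 of 7 cases, Vwf in 2, Fn1 in 3, and Mal and Cxcl12 in 4. Blood endothelium held a cluster led by Postn, Cox4i2 and Higd1b, markers of pericytes, with 56 cells at day 14 and 20 at day 24. It also held a cluster with C1qa, Scgb1a1, Lyz2 and Apoe, genes of macrophages and club cells, among its 10 leading genes, with 238 and 208 cells. Per1, Ahr, Dusp8, Bcl2l1, Stab1, Spp1, Apoe, Mmp12 and Sftpc passed with any 1 mouse left out. The number of called genes moved between 31 (without the day 14 mouse of hashtag 3) and 113 (without the day 24 mouse of hashtag 4). Ahr, Tnfrsf11b, Dusp8, Bcl2l1 and Stab1 were named after their values were seen.

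Within endothelium, aerocyte-like cells had 23 higher and 13 lower genes by edgeR and venous-like cells 18 and 9 (15 and 19 when scaled by total UMIs). In aerocyte-like cells Cxcl12 rose from 252 to 646 CPM (1.38 ± 0.22 SE, adjusted p = 0.00438, n = 3 and 4 mice) and the arterial transcription factor Sox17 from 102 to 195 CPM (0.96 ± 0.18). Mal rose from 3.17 to 25.1 CPM (2.64 ± 0.49) and Ildr2 from 0.277 to 19.5 CPM (5.33 ± 0.81). Ildr2 was near the floor at day 14, so the size of its change is not well determined. With 1 mouse left out Mal passed in 5 of 7 cases and Ildr2 in 3 of the 4 in which it was tested. Neither had a result with DESeq2 or after thinning. Dusp8 fell from 171 to 92.6 CPM (-0.87 ± 0.15), as did Bcl2l1 (-0.74 ± 0.14) and Stab1 (-0.59 ± 0.12). Cxcl12, Sox17 and Stab1 did not pass without doublet removal, nor Bcl2l1 and Stab1 with DESeq2, nor Sox17, Bcl2l1 and Stab1 after thinning. The class joined 2 clusters that held 50.2% and 49.8% of it at day 14 and 65.7% and 34.3% at day 24. In venous-like cells the imprinted gene Mest (-1.22 ± 0.17) and Ccnd1 (-0.96 ± 0.16) fell and Cxcl12 rose (0.88 ± 0.17), of which Ccnd1 did not pass after thinning and Cxcl12 passed in 3 of 7 cases with 1 mouse left out. In fibroblasts of the pooled sort 19 genes were higher and 7 lower, among them Dnajb1 (0.87 ± 0.14), Jun (0.60 ± 0.10) and P2ry14 (1.47 ± 0.18), all higher, of which Jun did not pass without doublet removal and P2ry14 after thinning. These genes were chosen after their values were seen.

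In SPP1 macrophage-like cells 17 genes were higher and 10 lower of 7978 tested. Spp1 (ENSMUSG00000029304, chromosome 5, 104435111 to 104441053) fell from 10898 to 6216 CPM (log2 change -0.81 ± 0.16 SE, edgeR adjusted p = 0.0398, n = 3 and 4 mice) and Fcrls from 191 to 106 CPM (-0.85 ± 0.14). The chemokine gene Ccl9 fell from 1865 to 1276 CPM (-0.54 ± 0.09), Lpl from 2985 to 2045 CPM (-0.54 ± 0.11) and the lipase gene Daglb from 174 to 111 CPM (-0.64 ± 0.12). Spp1 and Lpl were also among the markers used to name this class. In pooled CPM Spp1 was lower too in interstitial macrophage-like cells (log2 ratio -1.70), fibroblasts of the pooled sort (-0.90) and alveolar macrophage-like cells (-0.14). It was higher in fibroblasts of the PDPN sort. The stress-response gene Atf3 rose from 373 to 624 CPM (0.74 ± 0.11) and the cell cycle inhibitor Cdkn1a from 213 to 336 CPM (0.65 ± 0.12). The adhesion receptor gene Adgre5 rose from 50.2 to 94.0 CPM (0.93 ± 0.15) and Mir6236 by 1.43 ± 0.21. Of 14 genes of the SPP1 macrophage list 2 fell, and 5 adjusted over the list alone (median -0.09, and 0.043 without doublet removal, camera adjusted p = 0.00222, adjusted p = 0.262 with an estimated correlation). Cxcl12 (7.99 to 53.6 CPM, 2.82 ± 0.30) and Sftpc (1.31 ± 0.24) rose below the 10% screen. Cdkn1a, Adgre5, Spp1, Ccl9, Fcrls, Lpl, Daglb and Sftpc did not pass without doublet removal. After thinning these except Spp1 did not pass, nor did Atf3. Cxcl12 had no result without doublet removal. With 1 mouse left out Cxcl12 passed each time, Atf3 in 5 of 7 cases, Spp1 in 3, and Lpl and Daglb in 2. In interstitial macrophage-like cells 9 genes were higher and 1 lower. Fkbp5, a gene induced by glucocorticoids, fell from 78.4 to 28.0 CPM (-1.36 ± 0.25, adjusted p = 0.0457). Atf3 (187 to 345 CPM, 0.96 ± 0.14) and Acp5 (0.73 ± 0.12) rose. Il1b (1.01 ± 0.19) and Sftpc (1.74 ± 0.21) rose below the screen. Acp5, Il1b and Sftpc did not pass without doublet removal, nor Fkbp5 and Acp5 after thinning, and Fkbp5 passed in 2 of 7 cases with 1 mouse left out. Of 12 genes of dissociation and heat shock 1 rose there, and 6 adjusted over the list alone (median 0.42, camera adjusted p = 5.3e-08, adjusted p = 0.47 with an estimated correlation). In alveolar macrophage-like cells 6 genes were higher and 3 lower. S100a11 rose (586 to 866 CPM, 0.58 ± 0.10), Socs3, an inhibitor of cytokine signalling, fell (225 to 111 CPM, -0.97 ± 0.16). Mir6236 rose from 205 to 610.0 CPM (1.58 ± 0.14, adjusted p = 1.36e-05) and, below the screen, Scgb1a1 rose by 1.69 ± 0.17, while Mgp (-1.02 ± 0.12) and Col3a1 (-1.88 ± 0.33) fell. With 1 mouse left out S100a11 and Col3a1 passed in 3 of 7 cases and Socs3 in 4. Col3a1 had no result with DESeq2 or after thinning. Ear1 (1.41 ± 0.28, adjusted p = 0.0635) and Mgll (1.18 ± 0.23, adjusted p = 0.0612) did not pass. Of 10 alveolar macrophage genes 0 passed over all genes and 5 rose adjusted over the list alone (camera adjusted p = 5.79e-07, adjusted p = 0.21 with an estimated correlation). Of 6 matrix genes 1 fell and 3 adjusted over the list alone (camera adjusted p = 6.15e-07, adjusted p = 0.0446 with an estimated correlation). The fibroblast transcript Mgp was also lower in other classes of the pooled sort, such as SPP1 macrophage-like cells (log2 ratio of pooled CPM -1.45) and lymphocytes. In interstitial macrophage-like cells this ratio was -0.28. Outside the list members, the macrophage genes were named after their values were seen.

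In lymphocytes most genes that passed were transcripts more abundant in other classes. They were named after their values were seen. In Treg-like cells Scgb1a1, a secretory protein of airway club cells (3.33 ± 0.32 SE, edgeR adjusted p = 2.63e-08, n = 3 and 4 mice), Sftpc (2.35 ± 0.44) and AY036118 rose. Spp1 (-2.79 ± 0.30), Fn1 (-2.18 ± 0.38), Mgp (-1.18 ± 0.19), Lyz2 and Apoe (-0.98 ± 0.19) fell. In B cell-like cells Scgb1a1 (2.42 ± 0.32) and AY036118 rose and Lyz2 (-1.52 ± 0.18), Spp1 (-1.48 ± 0.31) and Mgp (-1.11 ± 0.24) fell. In gamma delta T-like cells Scgb1a1 (2.13 ± 0.32) and AY036118 rose and Spp1 (-2.55 ± 0.28), Lyz2 (-1.27 ± 0.18), Apoe (-1.27 ± 0.18), Mgp (-1.28 ± 0.24) and mt-Nd1 (-0.47 ± 0.10) fell. With DESeq2 Sftpc, AY036118, Fn1, Lyz2 and Apoe did not pass in Treg-like cells, nor Spp1 and Mgp in B cell-like, nor Mgp and mt-Nd1 in gamma delta T-like cells. Mgp did not pass without doublet removal in Treg-like and gamma delta T-like cells. After thinning AY036118 did not pass in Treg-like cells, nor Mgp in B cell-like, nor Apoe, Scgb1a1 and mt-Nd1 in gamma delta T-like cells. Fn1 and Sftpc in Treg-like, Scgb1a1 and Spp1 in B cell-like and Spp1 in gamma delta T-like cells had no result after thinning. Spp1 and Scgb1a1 in gamma delta T-like cells had none without doublet removal. Transcripts that overlap ribosomal RNA (AY036118, Gm42418, Mir6236 and Lars2) were on average higher at day 24 in all 15 classes tested (mean log2 change 0.54, from 0.10 to 0.85), although Gm42418 and Lars2 were lower in B cell-like (-0.24 and -0.44), Treg-like and gamma delta T-like cells and Lars2 in blood endothelium (-0.05).

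**Figure D4:**
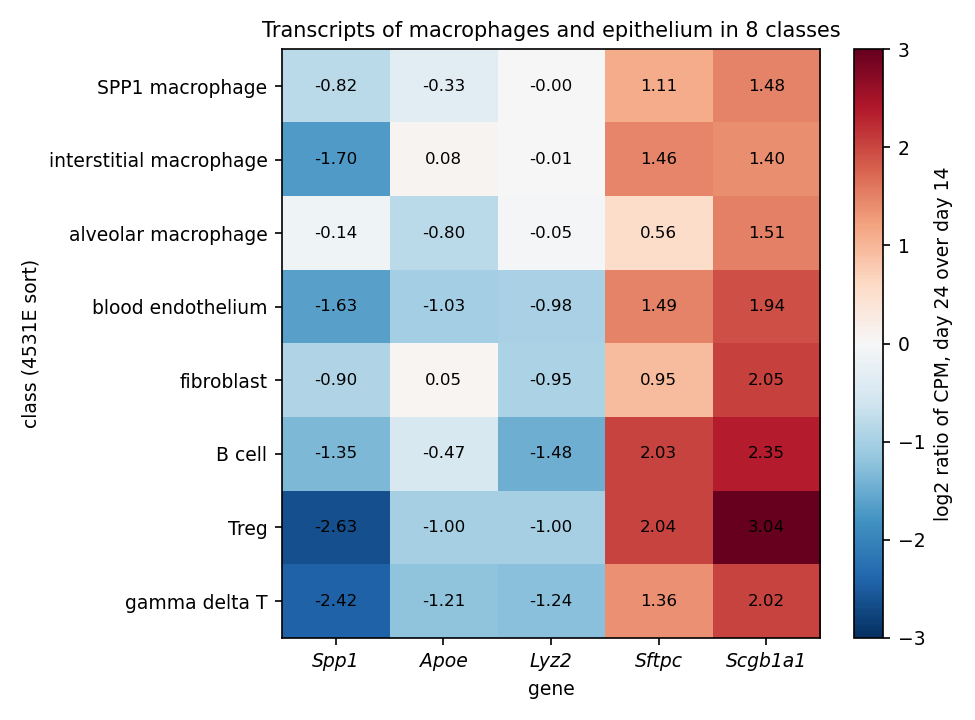
Log2 ratio of pooled CPM, day 24 over day 14, of 5 transcripts of macrophages and epithelium (x axis) in 8 classes of the pooled sort (y axis), with 5 CPM added to each value. Spp1, Apoe and Lyz2 are markers of macrophages, and Sftpc and Scgb1a1 of epithelium. Fibroblasts also expressed Spp1 (2659 and 1426 CPM), and Lyz2 was also among the leading genes of AT2-like cells.

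**Figure D5:**
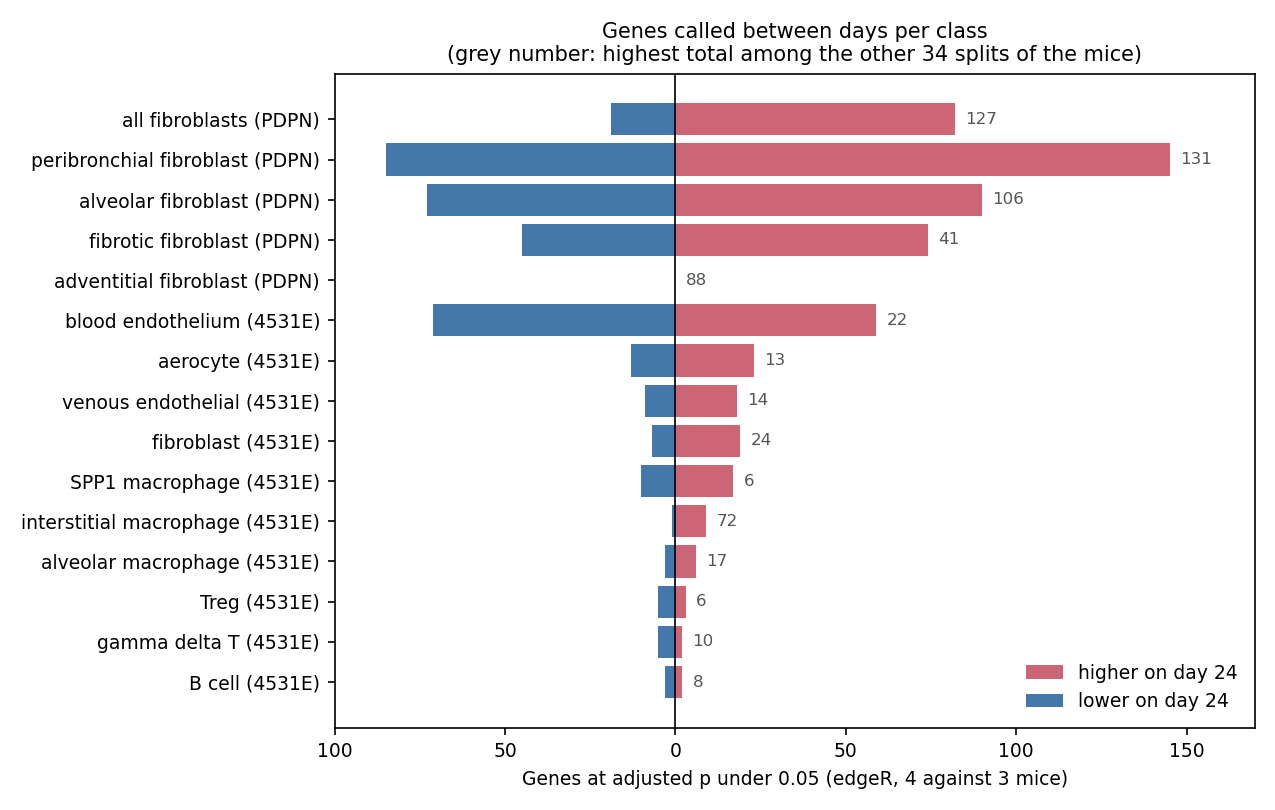
Number of genes higher (right) and lower (left) at day 24 by edgeR at an adjusted p under 0.05 in 15 classes (4 against 3 mice), such as 145 and 85 in peribronchial fibroblast-like cells. Grey numbers are the highest count that any of the other 34 splits of the 7 mice gave.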

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

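The tests of free RNA in endothelium and the test of captures for transcripts that overlap ribosomal RNA were chosen only after the result was seen, and the spread of the composition value without 1 mouse was added after that value was seen.

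The first pattern weighed was the higher level of Grem1, Dkk2, C1qtnf3 and Frzb and the lower level of Mmp8 and Myc at day 24 among the 101 genes called in all fibroblasts. With the composition of the 15 fibroblast clusters set equal on both days, the median absolute log2 change of these genes kept 74.2% of its size (0.39 against 0.53, between 70.6% and 76.6% without 1 mouse) and all 101 kept their direction. A change in cluster shares may thus account for part of the size, and the value argues against it as the whole cause for these genes as a set. The value was not computed for single genes, for which this cause stays open. C1qtnf3, for example, was among the leading genes of a cluster with 348 cells at day 14 and 1419 at day 24. Of the called genes measured in fibroblasts of the pooled sort 89.0% had the same direction there (73 of 82, against 58.2% of all genes), although only 2 were called there. This argues against an effect of the PDPN captures alone. Fibroblasts of the pooled sort without a hashtag call did not enter these values. Chance could not be excluded: 2 of the 35 splits of the 7 mice called as many genes (real 101, highest other 127), and the difference of day 14 and 24 in biology and in capture cannot be told apart in this design.

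The second pattern was the change of Spp1, Apoe, Mmp12 and Sftpc, genes of macrophages and epithelium, in blood endothelium. Fibroblasts of the pooled sort also expressed Spp1 (2659 and 1426 CPM). Of the 42 called genes under the 10% screen, 30 had at least 50 UMIs in lymphocytes and 100% of these had the same direction there. The change in UMIs per cell in lymphocytes was 0.734 of that in endothelium at the median of the 42, so free RNA of other cells is a candidate explanation that these values leave undecided. Of the 88 called genes that reached 10%, such as Per1, Mal, Cxcl12 and Vwf, 49 had at least 50 UMIs in lymphocytes, and 87.8% of these (43, against 58.0% of all genes) had the same direction there. The change in UMIs per cell in lymphocytes was 0.0244 of that in endothelium at the median of the 88 (upper quartile 0.358), and 0.253 at the median of the 49 (upper quartile 0.548). The share with the same direction met the outcome set for free RNA as a cause, while the amount did not. Free RNA in equal amount per droplet would give a ratio near 1, so the amount argues against it as the whole cause for these genes as a set. For the 15 of them with a ratio of at least 0.5 it stays open. A difference between the captures that acts on all cells stays open.

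The third pattern was the higher mean of AY036118, Gm42418, Mir6236 and Lars2, which overlap ribosomal RNA, at day 24. A difference between the captures that acts on all cells alike would change it alike in the classes of a sort. Between the 8 classes of the pooled sort that do not overlap it ranged from 0.18 (B cell-like) to 0.83 (alveolar macrophage-like), a spread larger than in the other 34 splits of the mice (exact permutation p = 0.0286, from means over mice instead of pooled CPM), which argues against such a difference as the whole cause. A difference between the captures that acts unequally on the classes stays open. Thinning each cell to 2000 UMIs kept 92.3% of it. Random thinning leaves the expected share of each transcript in a cell unchanged, so this value cannot decide whether lower depth of the day 24 libraries was a cause. No biological explanation was tested for this pattern.

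For the counts of called genes, the real split of the mice was compared with the other 34. The real split called the most genes in alveolar fibroblast-like cells (163 genes, highest other split 106), peribronchial (230 and 131) and fibrotic (119 and 41). It did so too in blood endothelium (130 and 22), SPP1 macrophage-like (27 and 6), aerocyte-like (36 and 13) and venous-like cells (27 and 14). In Treg-like cells (8 and 6) and fibroblasts of the pooled sort (26 and 24) it did so by a small margin. In these classes 1 of 35 splits was as large, the smallest share this comparison can give. It was not adjusted over the classes, some of which overlap, so it argues against chance in single classes without excluding it. In adventitial fibroblast-like cells 0 genes were called, so all 35 splits had to give as many and the comparison says nothing about chance (highest other 88). More than 1 split, the real one included, called as many genes in interstitial (3 splits, 10 and 72) and alveolar macrophage-like cells (2 splits, 9 and 17). The same held for B cell-like (4 splits, 5 and 8) and gamma delta T-like cells (2 splits, 7 and 10), so chance was not excluded in these 4 either. In the PDPN sort the highest other splits of the adventitial, alveolar and all-fibroblast comparisons set the day 24 mouse of hashtag 4 with the day 14 mice of hashtags 2 and 3. In the pooled sort those of interstitial macrophage-like cells and blood endothelium joined the same hashtags, which are not known to mark the same mice in both sorts. Such a split called several times the real number in the interstitial class and 88 genes against 0 in the adventitial class. This points to a structure of the samples beside the day. In blood endothelium it called fewer genes than the real split (22 against 130). In peribronchial and fibrotic fibroblast-like cells the highest other split joined the PDPN mouse of hashtag 4 of day 24 to the 3 mice of day 14.

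The effect of day differed between alveolar and adventitial fibroblast-like cells in 17 genes (highest other split 11, 1 of 35 as large) and between fibrotic and alveolar fibroblast-like cells in 29 genes (highest other 5, 1 of 35). These pairs were chosen after the calls of the real split were seen, so the comparison does not exclude chance. Between peribronchial and adventitial fibroblast-like cells it differed in 65 genes, but 2 of 35 splits gave as many (highest other 113), so chance was not excluded. Alveolar minus adventitial, the differences were -0.94 for Ccnd1, 0.61 for Dnajb1, 0.51 for Hspa1b, 0.70 for Hspa1a and 0.83 for Cd9. Peribronchial minus adventitial, they were 1.74 for Tmem119, 1.41 for Fam198b, 1.21 for Cthrc1, 0.52 for Ctsk, 0.76 for Fn1, 1.60 for Thy1, -0.97 for Plpp3, 0.59 for Pltp and 1.64 for Nkd2. Fibrotic minus alveolar, they were -0.57 for Thbs1, -1.42 for Rgs16, -0.65 for Adamts1, 0.73 for Aspn, 0.75 for Pdgfa and -0.70 for Npnt.

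In 12 of 193 groups of 4 mice tested, all of day 24, 1 mouse stood far from the others, and chance flags about 1 in 20 groups. The fibroblast classes here are of the PDPN sort and the endothelial classes of the pooled sort. A hashtag named for both may mark different mice in the 2 sorts. The mouse of hashtag 5 stood apart for Wisp1 (94.1 CPM, others 78.1 to 79.6) and Mmp11 (27.8 CPM, others 42.7 to 44.3) in alveolar fibroblast-like cells, Aspn in alveolar (114 CPM) and fibrotic fibroblast-like cells (219.7 CPM, others 102 to 117), and Ildr2 (54.4 CPM) and Dusp8 (60.2 CPM) in blood endothelium. The mouse of hashtag 4 stood apart for Ankrd1 in peribronchial (8.96 CPM) and Dkk2 in fibrotic fibroblast-like cells (128 CPM, others 243 to 259) and Mmp12 in blood endothelium (5.74 CPM). The mouse of hashtag 2 stood apart for Tgfb2 in fibrotic fibroblast-like cells (149.9 CPM) and Bgn in blood endothelium (71.4 CPM), and that of hashtag 1 for Bcl2l1 in aerocyte-like cells (51.8 CPM).

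Hashtags that the authors' note does not list for a library had 51 UMIs (PDPN, day 14), 37 (PDPN, day 24), 49 (pooled, day 14) and 40 (pooled, day 24), data that no comparison used.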

How the results depend on the processing

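Total UMI scaling, DESeq2, no low-count filter, thinning and no doublet removal for the edgeR counts, clustering without day genes and the earlier naming rules were chosen after the data were seen. No analysis paired the 2 sorts or the 2 days because the note does not say whether a hashtag is the same mouse in both sorts, and the mice of the 2 days differ. The strict filter, more variable genes and 1 hashtag only moved none of the 15 shares by more than the spread between mice, and total UMI scaling and TMM scaling moved none of the total counts of genes by more than 1.5 times, although under total UMI scaling the lower genes alone went from 71 to 113 in endothelium and from 9 to 19 in venous cells. Of 161 called gene results named, 154 kept their call under total UMI scaling, 143 with DESeq2, 123 without doublet removal, 109 after thinning and 60 with each mouse left out. Outside the cases with a mouse left out, a gene without a result in a setting was not counted as kept. Without doublet removal the share differences were -5.39 points for alveolar fibroblasts, and the medians turned for alveolar identity in adventitial fibroblasts (-0.022), the SPP1 list (0.043) and the general capillary list (-0.058) in SPP1 macrophages. The alveolar fibroblast difference was -2.74 clustered without day genes and 2.01 at resolution 0.5, the interstitial macrophage difference -0.560 under the lenient filter, the transitional epithelial -6.92 at resolution 2 and AT1 -2.55 under the first naming rule. Except where fewer genes or cells entered, the cause was not tested.

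Without the low-count filter edgeR called 286 genes in all fibroblasts, 625 alveolar, 595 adventitial, 610 peribronchial, 880 fibrotic, 697 in endothelium, 119 aerocyte, 112 venous, 347 in fibroblasts of the pooled sort, 219 in SPP1, 131 interstitial and 105 alveolar macrophages, 17 in B cells and 11 in gamma delta T cells. DESeq2 called 416 in all fibroblasts, 150 adventitial, 233 fibrotic, 68 in fibroblasts of the pooled sort, 20 in alveolar macrophages, 3 in Treg and 3 in B cells. Of the 101 genes of all fibroblasts DESeq2 called all 101. Without doublet removal edgeR called 18 in alveolar, 24 in interstitial and 8 in SPP1 macrophages, 19 in aerocytes and 11 in B cells. After thinning it called 57 in all fibroblasts, 125 peribronchial, 8 adventitial, 11 in SPP1 macrophages, 13 in aerocytes, 7 venous, 3 in B cells and 3 in gamma delta T cells. Leaving out 1 mouse, counts ranged over 2 to 184 (all fibroblasts), 0 to 220 (alveolar), 0 to 106 (adventitial), 58 to 373 (peribronchial), 14 to 463 (fibrotic), 31 to 113 (endothelium), 8 to 35 (SPP1), 4 to 48 (interstitial), 6 to 39 (alveolar macrophages), 10 to 45 (aerocyte), 11 to 51 (venous), 7 to 42 (fibroblasts of the pooled sort), 7 to 11 (Treg), 3 to 8 (B cells) and 5 to 7 (gamma delta T cells).

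Genes changed at least 2-fold numbered 9 in all fibroblasts, 3 alveolar, 12 adventitial, 23 peribronchial, 20 fibrotic, 4 in endothelium, 9 in SPP1, 8 interstitial and 3 in alveolar macrophages. With a minimum of 100 CPM they were 3 (all fibroblasts), 6 (adventitial), 8 (peribronchial), 0 (endothelium), 3 (SPP1), 3 (interstitial) and 1 (alveolar macrophages). Without the screen they were 5 (alveolar fibroblasts), 9 (endothelium), 27 (SPP1), 15 (interstitial) and 7 (alveolar macrophages). Thinned they were 12 (alveolar fibroblasts), 25 (SPP1), 26 (interstitial) and 16 (alveolar macrophages), and without doublet removal 14 (alveolar fibroblasts) and 16 (interstitial). Thinning turned the balance in macrophages. Higher and lower genes went from 8 and 1 to 9 and 16 (SPP1), and from 6 and 2 to 12 and 14 (interstitial). In alveolar macrophages they went from 3 and 0 to 4 and 12. A pseudocount of 1 gave 18 (all fibroblasts) and 7 (alveolar), the mean over cells 11 (alveolar), and equal weight per mouse 7 (alveolar fibroblasts) and 5 (alveolar macrophages). Leaving out 1 mouse, they ranged over 9 to 18 (all fibroblasts), 4 to 17 (alveolar), 9 to 19 (adventitial), 17 to 39 (peribronchial), 14 to 33 (fibrotic), 3 to 9 (endothelium), 7 to 13 (SPP1), 6 to 24 (interstitial) and 2 to 9 (alveolar macrophages).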

Other observations

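The levels of ligands by class were read after the comparisons above and were chosen after their values were seen. Among the classes of the pooled sort with at least 100 cells on a day, which left out ILC2-like cells (29 and 32 cells) and neutrophil-like cells (66 and 98 cells), Areg, a ligand of the EGF receptor, was highest in Treg-like cells (681 CPM at day 14 and 929 at day 24, from 571 and 551 UMIs pooled over mice). Il1b was highest in cDC2-like cells (3950 and 3685 CPM), Osm (569 and 702 CPM) and Tgfb1 (347 and 348 CPM) in alveolar macrophage-like cells, Il17a in gamma delta T-like cells (93.4 and 61.1 CPM) and Ccl2 in classical monocyte-like cells (530 and 331 CPM). The monocyte class was led by interferon-induced genes. Immune clusters without a name were ranked only as a pool (Ccl2 327 and 214 CPM). A cluster in that pool was led by Ccl4, Ccl3, Ccl7 and Ccl2 (98 and 195 cells) and may stand higher by itself. Edn1 (251 and 281 CPM) and Pdgfb (305 and 320 CPM) were highest in blood endothelium. Fibroblasts of the PDPN sort had 5492 and 6605 CPM of Spp1, 856 and 995 CPM of Igf1 and 184 and 230 CPM of Inhba. In fibroblasts of the pooled sort Spp1 went the other way, with 2659 and 1426 CPM.

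With all fibroblasts taken as 1 class (621 and 590 CPM), mural-like cells had the highest Postn of the PDPN sort (2392 and 2687 CPM). Il4 and Il13 had at most 9 UMIs in the class of the pooled sort with their highest CPM among classes of at least 100 cells, too few to call expression there at this depth. None of these differences between days was tested in addition to the comparisons above.

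Of 4 cells at day 14 and 144 at day 24, a cluster of the pooled sort mixed markers of several compartments and entered no comparison.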
